A study of Caenorhabditis elegans with 2 samples.

How the data were processed

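The series profiled the binding of the forkhead transcription factor FKH-2 in whole L3 larvae of Caenorhabditis elegans by chromatin immunoprecipitation and sequencing (ChIP-seq). Per the labels, the animals were a mixed-sex population of strain OP185, which carries the unc-119(ed3) mutation and the integrated transgene wgIs185, and the target was FKH-2 fused to enhanced green fluorescent protein (eGFP-fkh-2). The strain therefore holds tagged fkh-2 beyond the endogenous gene. The antibody label reads fkh-2, and whether the antibody binds eGFP or FKH-2 is not stated, so endogenous FKH-2 is not excluded as a source of signal. The labels name 2 biological replicates of 1 group. No second condition and no control library was analysed here.

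The authors deposited 4 peak lists per genome build (ce10 and ce11): 1 list for each replicate, 1 list for both replicates pooled, and an optimal set kept by irreproducible discovery rate (IDR), a threshold meant to retain peaks whose ranks repeat between replicates. Per the deposited text files, the replicate and pooled lists were derived from alignments together with a control file, and the IDR set was derived from the pooled list and both replicate lists. The replicate and pooled lists were the input for IDR and so hold weak regions as well as strong ones. The aligner, peak caller, their versions and the IDR threshold were not given in the sources used here. Each peak has a score, the signal value that the authors' caller gave it, and a −log10 of the q-value deposited beside it. The scale of the score was not given, so it served only to rank and describe peaks within a list. All ce11 IDR peaks shared 1 deposited −log10 (q-value) of 3.37, so no stricter q threshold could be set within that set. The deposited peak point lay at the centre of the peak, apart from 1 narrowed peak, and is called the peak centre here.

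Read numbers are not in the lists, so sequencing depth was unknown, and the precision of each share follows from the number of peaks behind it. Shares carry Wilson 95% intervals, which cover counting error over peaks only, and the upper bounds of 0 peaks are Wilson limits. For 0 genes of the joined neuronal lists, the limit is 3 counts of the total. P-values over peaks or genes describe these lists, since neighbouring regions are not independent animals.

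The ce11 lists were the main data. Ensembl release 115 gene models and the matching genome sequence gave the annotation, with 19973 protein-coding genes on the 6 nuclear chromosomes. Annotation and sequence of ce10 were not used here, so the ce10 lists entered only counts, scores, overlaps and chromosome shares. A peak was assigned to the protein-coding gene with the nearest transcription start site (TSS) within 2000 bp of its centre, and a promoter peak had its centre within 500 bp of such a site. Genomic features were exclusive, in the order 5′ UTR, CDS, 3′ UTR, intron of a protein-coding gene, intergenic. Intergenic meant outside protein-coding genes, so noncoding genes there counted as intergenic.

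Promoter and feature shares were tested by circular permutation, in which all IDR peaks of a chromosome were moved together by a random distance, 1000 times, two-sided. The same shifts, one-sided, served the overlap of the strongest peaks of the replicates (at least 1 bp) and the share of peaks within 200 bp of noncoding genes. The smallest p these can give is 0.001 one-sided and 0.002 two-sided. Chromosome shares were compared with those of the pooled peaks outside the IDR set by Fisher's exact test. Motifs were searched on both strands within 50 bp of each peak centre and in equal windows centred 500 bp to either side, and compared with the flank at lower coordinates by an exact McNemar test. Correlations across peaks used permutation tests with 100000 resamples. Gene lists were compared with all other protein-coding genes by two-sided Fisher's exact tests. Benjamini-Hochberg adjustment covered the 20 lists, the 8 motifs, the 6 chromosomes, the 5 features and the 9 noncoding classes, each as a family.

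The lists, motifs, tests and the rule for named genes were fixed before the data were examined. The rule took the genes of the 15 strongest IDR peaks that overlapped a peak of each replicate, up to 4 members of each list with an adjusted p under 0.05, up to 3 members of the cilium, sensory signalling, forkhead and pharynx lists, and fkh-2 and unc-119. Other genes named were chosen after their values were seen. Alternatives covered the genome build, the strongest peaks of either replicate in place of the IDR set, stronger and looser sets, windows, backgrounds, and the gap to the next gene upstream. Added alternatives compared list genes with genes of like assignable territory, the bases nearest to a TSS of the gene within 2000 bp, by an exact stratified test over 20 strata or a logistic model. Leaving out a replicate meant taking the 203 strongest peaks of the remaining replicate's own list.

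The tests were checked on simulated data. With 200 peaks placed at random, the promoter test passed 0.05 in 5 of 100 simulations, and in 100 of 100 when 20% of the peaks were moved to a TSS. The motif test passed in 6 of 100 simulations without an effect and in 98 with the forkhead core written into 20% of the centres. With 140 bound genes drawn at random, no list passed in 100 simulations, and the ribosomal protein list passed in all 100 when 6 of its genes were bound. Simulated genes were drawn regardless of assignable territory, and simulated peaks were placed without regard to GC. These rates therefore do not cover differences in territory or in GC between centre and flank. Calculations used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6 and Matplotlib 3.10.9.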

Results

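FKH-2 binding was mapped in L3 larvae, the larval stage that precedes the last larval stage before adulthood, from 2 biological replicates of whole animals carrying eGFP-tagged FKH-2. FKH-2 is a forkhead protein, a family of transcription factors with a winged-helix DNA-binding domain. The IDR set held 203 peaks in ce11, covering 58.7 kb or 0.0585% of the genome. Peaks were 290 bp wide except for 1 of 78 bp, and scores ran from 22.2 to 85.4 with a median of 27.4. The list of replicate 1 held 30000 peaks of 290 bp with a median score of 4.22, that of replicate 2 held 24744 peaks of 250 bp with a median of 3.31, and the pooled list held 30000. The lists ended at different deposited q-values, 0.356 in replicate 1, 0.541 in the pooled list and 0.0502 in replicate 2. Their counts and median scores are therefore not directly comparable. Every IDR peak was present in the pooled list with the same score, and together they were its 203 highest-scoring peaks. Membership thus coincided with a cut on the pooled score, and the rank of a single peak need not repeat. Among the IDR peaks, 37 were in the 203 strongest of neither replicate. The scores are the authors' own values.

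The 6 strongest FKH-2 peaks had no protein-coding TSS within 2000 bp, although 41.6% of the peaks above the median score were at promoters. The highest score, 85.4, belonged to the 78 bp peak at chromosome II, 12102565 to 12102642, an intergenic region 2627 bp from the nearest TSS, that of Y17G7B.17 (WBGene00012468). It ranked 2 in each replicate, with scores of 50.6 and 27.98. Intergenic peaks at chromosome X, 9465756 to 9466045 (score 68.01) and 11094051 to 11094340 (67.2), and at chromosome II, 8787406 to 8787695 (64.7), came next. The peak at chromosome IV, 5593941 to 5594230 (62.1) lay in an intron of fkh-7, which encodes another forkhead factor, ranked 13 and 3 in replicates 1 and 2, and contained a forkhead core. The peak at chromosome X, 6296478 to 6296767 (52.3) lay in an intron of mom-1, a gene of Wnt ligand secretion. These genes were named after their peaks were seen, because no TSS was close enough for assignment. Besides the peak in fkh-7, only that at chromosome II, 8787406 to 8787695 had a forkhead core among these 6.

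Of the 15 strongest peaks, 6 were assigned to a gene. C04G6.2 (WBGene00015453, chromosome II, 5093231 to 5094218) had an intergenic peak 628 bp upstream of its TSS, with a score of 52.2. The gene of the AAA ATPase cdc-48.1 (WBGene00007352, chromosome II, 10560036 to 10563407) had one 156 bp upstream (48.3). The peak of the insulin-like peptide gene ins-13 (WBGene00002096, chromosome II, 5544512 to 5544864) lay downstream of the gene, 1159 bp from its TSS (47.8), and within 200 bp of the spliced-leader RNA gene sls-2.2. The taspase homologue tasp-1 (WBGene00010480, chromosome III, 10759307 to 10763021) had a peak 44 bp upstream (43.9). The chemoreceptor family gene srg-26 (WBGene00005183, chromosome V, 5331267 to 5333055) had one 1149 bp upstream, beside a tRNA gene (43.9). F55G7.5 (WBGene00195215, chromosome X, 11938130 to 11938926) had one 1376 bp from its TSS on the downstream side (43.9).

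The comparison between samples that the design holds is that of replicate with replicate. All 203 IDR peaks overlapped a peak in the list of replicate 1 and 195 overlapped one of replicate 2. The 2 libraries ranked these regions differently. Of the IDR peaks, 133 (65.5%, 95% interval 58.7 to 71.7) were among the 203 strongest of replicate 1, and 86 (42.4%, 35.8 to 49.2) among the 203 strongest of replicate 2. Between the 203 strongest peaks of the replicates, 53 (26.1%, 20.5 to 32.6) overlapped, against a mean of 0.245 after circular shifts (permutation p = 0.001, the smallest possible). Across the 195 shared IDR peaks, which are not independent replicates, the scores had a Spearman rho of 0.00790 (permutation p = 0.912) and a Pearson r of 0.173 (p = 0.0159; adjusted over the 2 coefficients, 0.912 and 0.0318). Without the 2 peaks farthest from the replicate 1 median, r was 0.0988. The choice of peaks by their pooled score restricts this correlation, and over the 5492 replicate 2 peaks that overlapped a replicate 1 peak, rho was 0.170 and r 0.408 (permutation p = 1e-05 for each, the smallest possible).

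**Figure D1:**
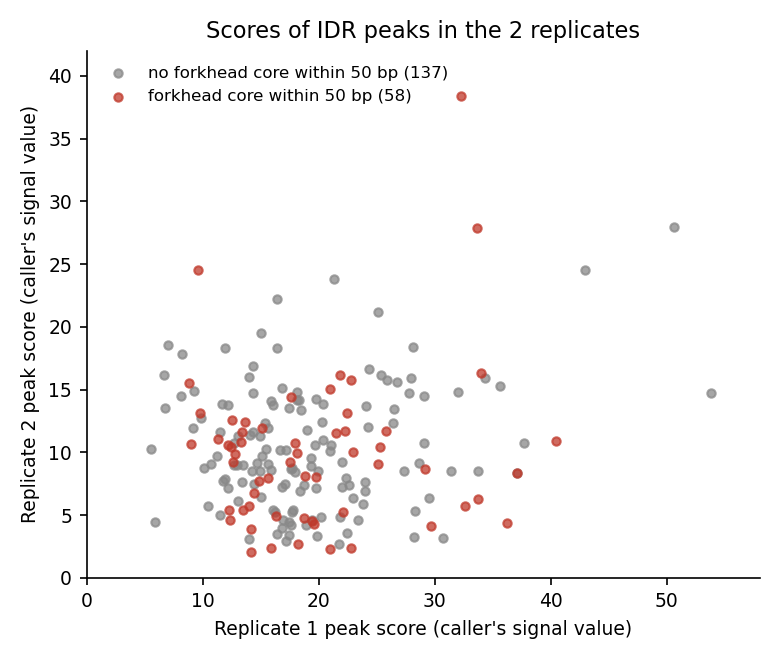
Score of each IDR peak found in both replicates, with the caller's signal value in replicate 1 on the horizontal axis and in replicate 2 on the vertical axis; each point is 1 peak, coloured by whether the forkhead core RYAAAYA lies within 50 bp of its centre. The 195 points show no common ranking (Spearman rho 0.00790), and the highest pooled score belongs to the point at 50.6 and 27.98.

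FKH-2 peaks lay in intergenic sequence and at promoters more often than shifted peaks, and less often in coding sequence. Intergenic centres, those outside protein-coding genes, made up 155 of 203 (76.4%, 70.1 to 81.7), against 37.5% after shifting and 35.8% of the weaker pooled peaks. Introns held 40 (19.7%, against 33.8% after shifting), coding sequence 3 (1.48%, against 23.6%) and 5′ UTRs 5 (2.46%, against 1.75%). None lay in a 3′ UTR, where an upper bound of 1.86% stands against 3.36% after shifting. Circular permutation gave an adjusted p of 0.00333 for the intergenic, intronic and coding shares, 0.00749 for 3′ UTRs and 0.531 for 5′ UTRs. Promoters held 77 peaks (37.9%, 31.5 to 44.8), against 22.3% ± 3.00 (SD over 1000 shifts; p = 0.002, the smallest possible) and 26.4% of the weaker pooled peaks (Fisher's exact p = 0.000413). The 297 pooled peaks ranked 204 to 500 had a share of 42.4%, so a high promoter share was not particular to the IDR set. The shifts do not separate promoters from other intergenic sequence. Assignment reached 141 genes, with 121 peaks upstream of the TSS, 21 at or downstream of it, and a median distance of 434 bp. The trehalase gene tre-2 alone had 2 assigned peaks, both intronic, at chromosome IV, 6878973 to 6879262 and 6881211 to 6881500. A further 61 peaks (30.05%) had no protein-coding TSS within 2000 bp, and 72 assigned peaks had more than 1 gene in reach, so the nearest gene is not shown to be the regulated one.

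**Figure D2:**
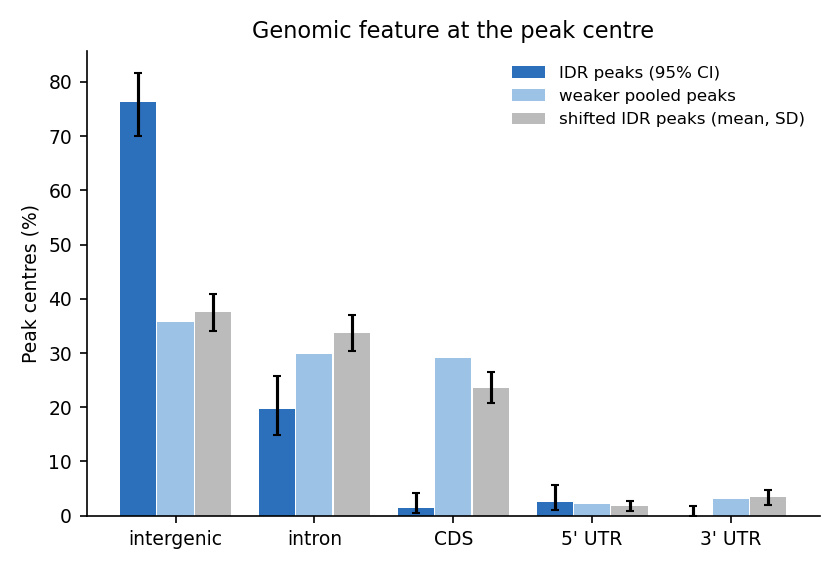
Share of peak centres in each genomic feature, in percent, for the 203 IDR peaks with Wilson 95% intervals, for the weaker pooled peaks, and for shifted IDR peaks as the mean and SD of 1000 circular shifts. The intergenic share of IDR peaks (76.4%) stands above both references (35.8% and 37.5%), and their coding share (1.48%) below both (29.2% and 23.6%).

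Chromosome X carried more of the IDR peaks than of the weaker ones, and chromosome V fewer. X held 55 peaks (27.1%, 21.4 to 33.6), against 19.03% of the weaker pooled peaks (odds ratio 1.58, Fisher's exact adjusted p = 0.0197). Chromosome V held 26 (12.8%, 8.89 to 18.1), against 20.5% (odds ratio 0.569, Fisher's exact adjusted p = 0.0197). Chromosomes I, II, III and IV had adjusted p from 0.637 to 0.921. Both differences kept their direction but were not past the threshold in either replicate alone. Among the 203 strongest peaks of replicate 2, X had 24.1% against 19.2% (odds ratio 1.34, Fisher's exact adjusted p = 0.177) and V 16.3% against 20.4% (0.757, adjusted p = 0.238). Among those of replicate 1, X had 24.1% against 18.9% (odds ratio 1.37) and V 14.8% against 20.1% (0.690, Fisher's exact adjusted p = 0.193 for both). In the stronger part of the IDR set, the peaks above its median score, the odds ratios were 1.47 for X (25.7%) and 0.574 for V (12.9%), with a Fisher's exact adjusted p of 0.295 for both.

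Forkhead cores and GAGA repeats were more frequent at FKH-2 peak centres than beside them. The degenerate core RYAAAYA, in which R is a purine and Y a pyrimidine, occurred at 60 centres (29.6%, 23.7 to 36.2). It occurred in 15.8% of the flanks at lower coordinates, 21.7% of those at higher coordinates and 16.8% of the weaker pooled peaks (exact McNemar p = 0.00203 against the lower flank, adjusted p = 0.00812). The stricter core RTAAACA occurred at 31 centres (15.3%, 10.97 to 20.9), against 2.46% and 6.404% of the flanks (exact McNemar p = 1.29e-05). The repeat GAGAGA occurred at 78 centres (38.4%, 32.01 to 45.3), against 6.90% and 3.94% of the flanks and 8.04% of the weaker peaks (exact adjusted p = 2.63e-12). The GATA core WGATAR (11.3% against 20.2%, exact adjusted p = 0.0397) and the homeodomain core TAATTA (0.985% against 5.91%, adjusted p = 0.0345) were less frequent at the centres than in the lower flanks. The centres were also richer in GC (46.3%, against 35.9% in the lower flanks). No GC-matched reference was run for WGATAR or TAATTA, so base composition is not separated from their lower shares. E-boxes, AP-1 sites and SP1-like sites had exact adjusted p from 0.292 to 1, and the core of the X-box, bound by the RFX factor DAF-19 at ciliary genes, occurred at 0 centres (upper bound 1.86%, adjusted p = 1). The excess of RYAAAYA was not past the threshold against the higher flank (exact p = 0.0929), or in the 203 strongest peaks of replicate 1 (22.7%, p = 0.302) or of replicate 2 (25.6%, p = 0.207), whereas RTAAACA was in each of these (p = 0.00643, 0.00232 and 0.000546).

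**Figure D3:**
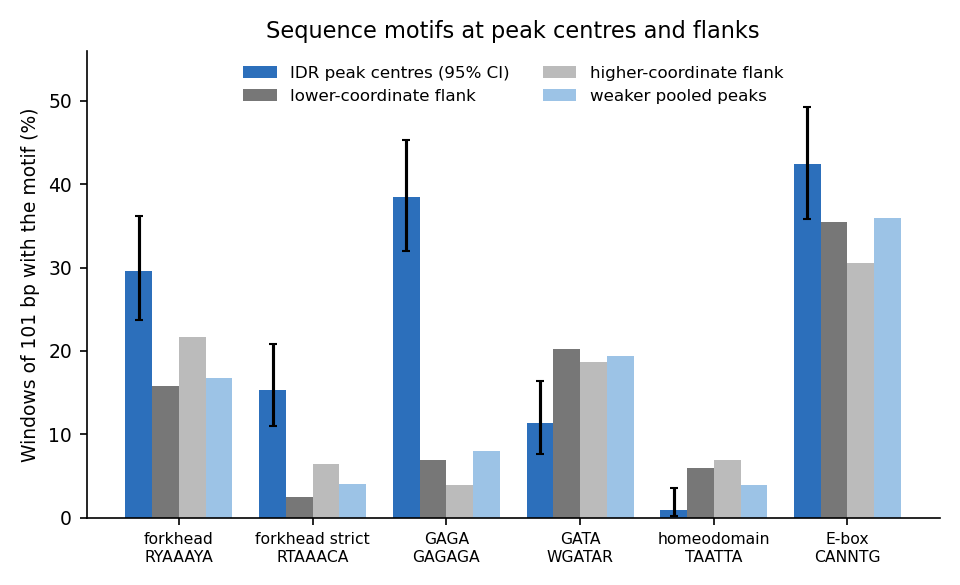
Share of windows reaching 50 bp to either side that hold each motif, in percent, at the 203 IDR peak centres (Wilson 95% intervals), in their flanks 500 bp to either side, and at the centres of weaker pooled peaks. GAGAGA (38.4%) and the stricter forkhead core RTAAACA (15.3%) stand above all 3 references, and TAATTA (0.985%) lies below them.

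Genes of developmental timing and of the cytosolic ribosome were over-represented among the 141 genes with an IDR peak. Among the heterochronic genes, which time larval cell fates, 3 of 14 had a peak (21.4%, against 0.691% of other genes; odds ratio 39.2, Fisher's exact adjusted p = 0.00237). lin-28 (WBGene00003014), which encodes an RNA-binding protein, had an intronic peak 50 bp upstream of a TSS at chromosome I, 8409825 to 8410114, with a score of 31.5. lin-66 (WBGene00001562) had an intergenic peak 225 bp upstream at chromosome IV, 13887709 to 13887998 (26.3). The transcription factor gene lin-14 (WBGene00003003) had an intronic peak 1925 bp downstream of a TSS at chromosome X, 11467340 to 11467629 (22.9). Of 81 cytosolic ribosomal protein genes, 5 had a peak (6.17%, against 0.684%; odds ratio 9.56, Fisher's exact adjusted p = 0.00272). rpl-3 (WBGene00004414) had one 283 bp upstream at chromosome III, 3867426 to 3867715 (42.3), and rpl-15 (WBGene00004427) one 404 bp upstream at chromosome IV, 654835 to 655124 (42.002). rpl-12 (WBGene00004424) had one 20 bp upstream at chromosome IV, 13240526 to 13240815 (31.3), a centre with TSSs of lin-54 and tag-115 also within 2000 bp. rps-1 (WBGene00004470) had one 258 bp upstream at chromosome III, 4475515 to 4475804 (26.9), and rps-15 was the fifth gene. Other genes also had a TSS within 2000 bp of the rpl-15, rps-1 and rps-15 peak centres. The rpl-15 peak held the forkhead core RYAAAYA within 50 bp of its centre. The peaks of lin-28, lin-66, lin-14, rpl-3, rpl-12, rps-1 and rps-15 did not. Neither call held in 1 replicate alone: with the 203 strongest peaks of replicate 1 the odds ratios were 0 for heterochronic genes and 7.17 for ribosomal protein genes (exact adjusted p = 1 and 0.0604), and with those of replicate 2 they were 10.9 and 3.598 (both adjusted p = 0.464). In the stronger part of the IDR set they were 21.5 and 11.05 (exact adjusted p = 0.465 and 0.0627).

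None of the genes listed beforehand as neuronal or ciliary was the nearest gene of an IDR peak. The cilium and intraflagellar transport (49 genes), sensory signalling (32), pan-neuronal (30), neurotransmitter identity (19) and homeobox and neural fate (48) lists each had 0. Together they hold 178 genes, for which 0 allows a share of up to 1.69% (3 counts of the total), above the 0.712% of other genes, so a lower share was not detectable (Fisher's exact p = 0.640). With every gene within 2000 bp of a peak centre counted, 1 of the 30 pan-neuronal genes was reached, the tubulin gene tba-1 (3.33% against 1.15% of other genes, exact adjusted p = 0.798), and the other 4 lists stayed at 0. The lists are not complete: outside them, and named after the peaks were seen, the ciliary transition zone gene tmem-231 had a peak 1677 bp downstream of its TSS (score 25.6) and the homeobox gene ceh-38 one 16 bp downstream (28.02). The intraflagellar transport gene ift-43, also unlisted, lay within 2000 bp of the peak assigned to mdt-26. In replicate 2, the peaks of tmem-231 and mdt-26 ranked 7457 and 17544. Other unlisted genes with an assigned peak included unc-63 (38.2), ins-39 (28.2), sol-1 (27.5) and eat-16 (23.2). The 0 of the lists therefore does not show that neuronal genes were absent from the set. The pharynx, intestine, hypodermis, germline, glia, vulval signalling and Wnt lists also had 0 (exact adjusted p = 1 for each list). Of 15 forkhead genes, fkh-7 had an assigned peak, in its intron at chromosome IV, 5607376 to 5607665, with a score of 24.8 and 842 bp upstream of a TSS (odds ratio 10.1, exact adjusted p = 0.661). No RYAAAYA lay within 50 bp of the centre of this fkh-7 peak. Single members of other lists were the co-chaperone gene dnj-13, the troponin T gene tnt-2, the proteasome subunit gene rpn-3 and the histone gene his-37, with 2 collagen genes, col-94 and col-181 (adjusted p from 0.661 to 1).

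Peaks also lay beside small noncoding RNA genes more often than shifted peaks did. The tRNA genes were tested because signal that does not depend on the antibody is common there. With no control library analysed, such signal is not separated from FKH-2 binding at any of these genes. Within 200 bp of a tRNA gene, transcribed by RNA polymerase III, lay 5 peaks (2.46%, 1.06 to 5.64), against 0.315% after shifting (permutation p = 0.001, the smallest possible; adjusted p = 0.00225). Small nuclear RNA genes had 7 peaks (3.45%, 1.68 to 6.95), against 0.0601%, among them the spliced-leader genes sls-2.1, sls-2.2, sls-2.4 and sls-2.8. Small nucleolar RNA genes had 4 (1.97%, against 0.176%), both classes with an adjusted p of 0.00225. Among the 203 strongest peaks of replicate 2, taken without replicate 1, 3.94% lay beside tRNA genes and 1.97% beside small nuclear RNA genes (permutation p = 0.001 for each). Long intergenic RNA genes had 4 (1.97%, against 0.318%, permutation adjusted p = 0.00899), and unclassified noncoding genes 42 (20.7%, against 3.76%, adjusted p = 0.00225). MicroRNA genes had 1 peak, beside cel-mir-52 (permutation adjusted p = 0.342), and ribosomal RNA genes had 0 (adjusted p = 1). Pseudogenes and piRNA genes each had 1 (0.493%), against 3.497% and 2.69% after shifting, and the one-sided permutation test, which looks for an excess only, gave an adjusted p of 1 for both.

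Neither fkh-2, the gene of the tagged protein, nor unc-119, the gene mutated in the strain, had an IDR peak within 20 kb. fkh-2 (WBGene00001434, chromosome X, 3740207 to 3742323) had 3 pooled peaks within 20 kb, or 0.0712 per kb, against 0.324 per kb on the rest of X (exact binomial p = 0.00151), and none within 5 kb. A stretch of 36.6 kb around it, from 3717433 to 3754061, held no listed peak in either replicate and also spans nlp-1, aex-4 and tag-18. unc-119 (WBGene00006843, chromosome III, 10902641 to 10908935) had 17 pooled peaks within 20 kb, or 0.367 per kb, against 0.319 per kb on the rest of III (exact binomial p = 0.514). The strongest of them ranked 3091 in the pooled list.

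**Figure D4:**
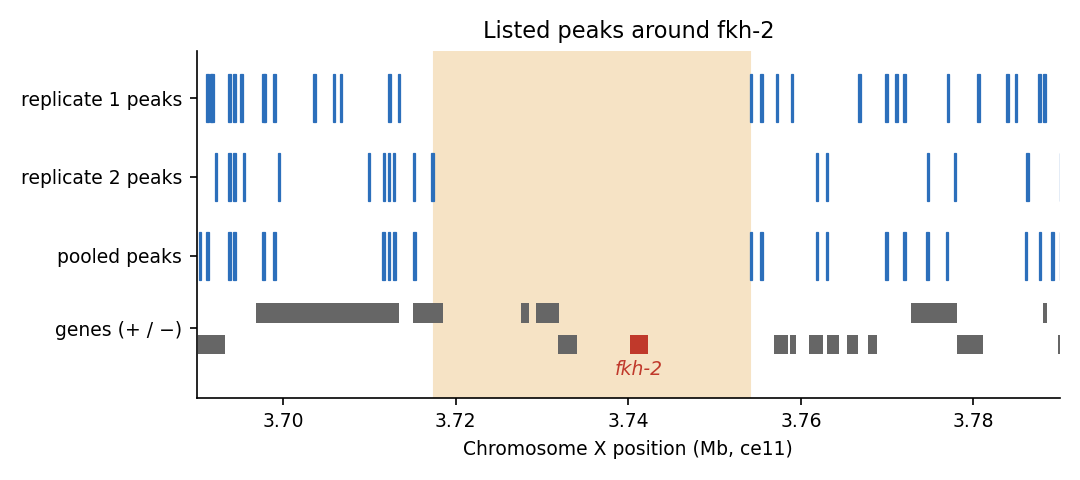
Peaks listed in replicate 1, replicate 2 and the pooled list (blue boxes) along chromosome X around fkh-2, with position in Mb on the horizontal axis and protein-coding genes below by strand (fkh-2 in red). The shaded stretch of 36.6 kb has no peak in either replicate, whereas listed peaks flank it on both sides.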

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

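The correlation over all overlapping replicate peaks, the tests at looser peak numbers or with assignable territory, and the alternatives for intergenic, small nuclear RNA, GAGA and strict forkhead shares were chosen after seeing the data. The shares at promoters, intergenic regions and tRNA and small nuclear RNA genes, the overlap of the strongest peaks, and the GAGA and strict forkhead shares kept their direction and their side of 0.05 in every alternative run. Without replicate 1, the share at tRNA genes rose from 2.46% to 3.94% and that at small nuclear RNA genes fell from 3.45% to 1.97%. The IDR set held 199 peaks in ce10. The excess of chromosome X was no longer past the threshold without replicate 1 or replicate 2 (24.1% in both) or in the stronger part of the IDR set (25.7%), and the deficit of chromosome V was not past it in the same 3 alternatives (16.3%, 14.8% and 12.9%). The excess of the forkhead core RYAAAYA (29.6%) was not past it against the downstream flank, nor without replicate 1 or replicate 2 (22.7% to 25.6%). The number of over-represented lists fell from 2 to 0 without either replicate and in the stronger part of the set, which holds fewer peaks. With a replicate left out, the heterochronic odds ratio ranged from 0 (without replicate 2) to 10.9 (without replicate 1). The score correlation between replicates had a rho of 0.170 and an r of 0.408 over all replicate 2 peaks overlapping a replicate 1 peak, where the pooled score no longer selects the peaks. For the changes with a replicate left out and with the flank, the cause was not tested. A q threshold 10 times stricter was not run, since all IDR peaks share 1 value, nor were annotation and sequence results in ce10. Sequencing depth is unknown, so the lists were not compared at equal depth. No paired analysis was possible because the series has 1 group.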

Other observations

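The tests of looser peak sets, the strata of assignable territory, the search over 6-mers, and the tests of chance and of transgene copies at fkh-2 were chosen after the results were seen. Heterochronic genes stood out further down the peak lists. Among the 1000 strongest pooled peaks, 6 of 14 had an assigned peak (42.9%, against 3.50% of other genes; odds ratio 20.7, Fisher's exact adjusted p = 8.92e-05), adding lin-41, lin-42 and myrf-1 to lin-14, lin-28 and lin-66. Among the 5000 strongest, 12 of 14 had one (85.7%, against 15.1%, exact adjusted p = 1.99e-07), including lin-29, the hormone receptor gene daf-12 and blmp-1. Most of these 5000 peaks lie outside the IDR set. The 3000 weakest of the 5000 held RYAAAYA in 17% of centres, against 18.1% of their flanks. A replicate 2 peak overlapped 53.5% of these 3000, and a replicate 1 peak 76.1%. Bound means having an assigned peak here and below, which at such ranks does not show FKH-2 binding. The heterochronic genes have much assignable sequence, a median of 5571 bp nearest to one of their TSSs within 2000 bp, against 2996 bp over all genes. Compared with genes of like territory, 1.11 of the 14 would be bound at 1000 peaks (odds ratio 9.05, exact stratified adjusted p = 0.00634) and 4.08 at 5000 (odds ratio 15.5, adjusted p = 0.000334). In each replicate's own 1000 strongest peaks, 6 of the 14 were bound in replicate 1 (stratified odds ratio 9.51, exact adjusted p = 0.00343) and 5 in replicate 2 (9.08, exact adjusted p = 0.0588, or 0.00954 in a logistic model). In the 5000 strongest of replicate 2, the stratified odds ratio was 2.75 (exact adjusted p = 0.966).

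Ribosomal protein genes have little assignable sequence, with a median of 1479 bp. Their stratified odds ratio was 6.98 in the 1000 strongest peaks of replicate 1 (exact adjusted p = 9.78e-05) and 2.94 in those of replicate 2 (exact adjusted p = 0.870). Heat shock genes had 4 of 20 bound at 1000 pooled peaks, dnj-13, hsp-1, hsp-3 and hsp-12.3 (stratified exact adjusted p = 0.0343). In the replicates' own 1000 strongest peaks, 5 were bound in replicate 1 (stratified odds ratio 10.6, exact adjusted p = 0.00343) and 1 in replicate 2 (2.01, exact adjusted p = 1), and at 5000 pooled peaks the exact stratified adjusted p was 0.254. With every gene within 2000 bp of an IDR centre counted, 4 of the 20 were reached (Fisher's exact adjusted p = 0.000730). Pan-neuronal genes had 11 of 30 bound at 5000 pooled peaks (Fisher's exact adjusted p = 0.0322), among them unc-10, unc-2 and unc-33, and a stratified adjusted p of 0.511. Cilium genes had 8 of 49 bound at 5000 peaks, 16.3% against 15.2% of other genes (exact adjusted p = 0.841). Of 2080 6-mers, 67 were more frequent at IDR centres than in the lower flank and 62 less (exact McNemar, adjusted p under 0.05). Besides GAGAGA, CGTCTC occurred at 22.7% of centres, against 0.985%, and GACGCA at 17.2%, against 1.97%, while AAAAAT occurred at 21.7%, against 52.2%. Only GAGAGA among these was compared with a GC-matched reference. CGTCTC reads GAGACG on the other strand, which overlaps both GAGAGA and GACGCA. These 6-mers and the counts of 6-mers are therefore not independent, and whether they mark the same sites was not tested.

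The stretch without peaks around fkh-2 was weighed against 3 technical explanations. Of 2731 protein-coding genes on X, 5 (0.183%) lay in a stretch at least as long without a peak in either replicate, 4 of them in this one, and over all chromosomes 90 genes (0.451%) did, which argues against a chance gap at this locus. Repeat-masked bases made up 25.5% of the stretch, against a median of 29.6% in X windows of its length, which argues against an excess of masked repeats. Masked bases do not measure whether reads can be placed, so unplaceable reads stay open. Extra copies of a transgene in the control reads may have raised the background there, and the 36.6 kb length is within 20 to 60 kb, the range set for a fosmid insert; the edges in the 2 replicates differed by 3.85 kb and 7.63 kb, more than the median peak spacing of 2.32 kb, and without control reads this stays open. No gap was seen at unc-119, the gene mutated in the strain (0.367 pooled peaks per kb within 20 kb, against 0.319 on the rest of the chromosome, exact binomial p = 0.514). Whether the transgene carries unc-119, and with how much flanking sequence, is not stated, so this result does not weigh for or against extra copies. No biological explanation was tested, since the design has 1 group.

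The GAGA repeats at IDR centres, which also had a GC content of 46.3% against 35.9% in the flanks, were weighed against 2 explanations. Weaker pooled peaks matched on GC held GAGAGA in 12.27% on average over 1000 draws, and in 20.7% at most, against 38.4% of IDR peaks, so base composition alone does not account for them. Recruitment that does not need a forkhead core could place such sites in the set. Peaks without the stricter core held GAGAGA in 37.8%, against 7.56% and 4.65% of their flanks (exact McNemar p = 1.28e-10), as this would give. Peaks with the core held it in 41.9% (Fisher's exact p = 0.691), not in a lower share, so this stays open. Apart from such recruitment, no biological explanation was tested.

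The different strongest peaks of the 2 replicates were weighed against 2 explanations. The prediction for fewer reads in replicate 2 alone was that nearly all of its 203 strongest peaks would be listed in replicate 1. The share was 69.95% (63.3 to 75.8, against 16.36% after shifting). In the other direction, 79.8% (73.8 to 84.7) of the 203 strongest peaks of replicate 1 were listed in replicate 2. Fewer reads could also make the strongest ranks of replicate 2 noisier, and depth is unknown, so these shares cannot decide. Centres of the strongest peaks had 3.804 percentage points more GC in replicate 1 than in replicate 2 (standard error 0.844), below the 5 points set as a bound but not by 2 standard errors, so base composition may contribute and stays open. IDR peaks among the strongest of both replicates held GAGAGA in 35.8%, against 39.3% of the other IDR peaks (Fisher's exact adjusted p = 0.824). No biological explanation was tested.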
